A study of Mus musculus with 3 samples.

How the data were processed

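The deposited count matrix of the single-cell library, UMI counts per gene and barcode, was made by the authors with Cell Ranger 8.0.1 on GRCm39, per the submitters' processing notes. The gene annotation version is not given in the sources used here. The matrix lists 21750 features, of which 21748 carry an Ensembl ID and 2 are the reporters EGFP and tdTomato. A symbol is shared by 2 or more IDs in 19 cases. The files hold 6672 barcodes, with 500.0 to 42440 UMIs each. The anti-Flag and IgG chromatin samples were not analysed here. Each of the 3 samples is alone in its group, mice were pooled, and no barcode can be assigned to a mouse.

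Barcodes with fewer than 500 genes (164) or over 15% mitochondrial UMIs (97) were removed, 187 in all, against a median of 1.23% mitochondrial UMIs. Doublets were called on the 6485 barcodes left with Scrublet in scanpy at an expected rate of 0.05, and 261 (4.02%) were removed. The 6224 cells analysed had a median of 5479.5 UMIs. Tools were Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Counts were scaled to 10000 UMIs per cell and log-transformed. Clustering used genes seen in at least 3 cells, 2000 highly variable genes without the genes of the lists and without the reporters, 30 principal components, 15 neighbours, Leiden resolution 1 and seed 0, and gave 23 clusters.

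Clusters were named from marker sets fixed before the data were examined. Of 132 marker symbols, 4 (Meg3, Trac, Trbc2 and Ighm) were not matched. A marker counted for a cluster if its CPM was at least 20 and at least 4 times the median over clusters. A cluster took the class with the largest share of its markers counted, if at least 3 were. It stayed unnamed if its 10 leading genes, those of largest ratio to all other cells with at least 100 CPM, held at least 2 more markers of another class than of its own. It also stayed unnamed if its median UMI count was under the sample median divided by 3 and no leading gene was a marker of its class. Clusters with more leading markers of another class than of their own are compared by number only. The exact naming rule was set after the clusters were seen. Astrocyte-like, neuron-like and oligodendrocyte-like cells were clustered again with 20 principal components, which gave 8 sub-clusters, a step added after the data were seen.

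UMIs were summed over the cells of a group and divided by the group's total. Ratios have exact 95% intervals from the binomial distribution, levels from the Poisson distribution and shares of cells by the Clopper-Pearson method. A share of 0 is given with the share that 3 cells would make. Log2 ratios use sums with 0.5 UMI added. Where a group had 0 UMIs, the ratio is a bound with 0 set to 3 counts over the group. No test across samples was possible. The 22 gene lists hold 426 genes, all among the features: the knockdown target and lists for astrocyte handling, gliogenic and neurogenic transcription factors, Notch, BMP and Wnt pathways, immature neuron, synaptic and channel genes, S phase and G2 and M phase, reactive astrocyte, interferon, immediate early, p53, stress response, cholesterol, glycolysis, fatty acid oxidation, oxidative phosphorylation and quiescent stem cell genes. A member was measured with at least 10 UMIs in both groups together, and higher or lower if its ratio interval lay wholly on one side of 1. Each list median was set against 10000 random lists matched on mean expression in 20 bins. Genes named are Hopx and the 12 list genes with the largest ratios in each direction, among those with at least 20 CPM in a group, a ratio of at least 2 and Poisson intervals that do not overlap. Not every gene this rule selects is reported here. Other genes are given as description of a cluster or as chosen after their values were seen.

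Shares of cells with a reporter, Hopx, cycling genes or both marker kinds are also given with cells thinned at random to 2000 UMIs, which 5699 cells reach. The count for cell cycle genes takes cells with at least 3 UMIs over both cycle lists, which does not measure division. The comparison by EGFP in ependymal-like cells was added after the reporter counts were seen. Gene comparisons were tested on simulated data with 200 changed genes each. For the sizes of the neuron-like and astrocyte-like groups, intervals held the true ratio for 97.6% of 8837 genes, the named-gene filter took 15% of genes set to a 2-fold and 61% of those set to a 4-fold change, and 32 of 7857 unchanged genes. A list set to a 2-fold change had a median of 0.90 and an unchanged list 0.03. For the EGFP comparison the values were 96.8% of 11719 genes, 41%, 93%, 25 of 7953, and medians of 0.99 and 0.15. Alternatives varied the cell filter, doublets, Leiden resolution, clustering genes, number of principal components, weighing of cells, lowest UMI count of list members and the cycling threshold. For the EGFP comparison they also varied the cells compared, their depth and the EGFP threshold.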

Results

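Single-cell RNA was measured in 1 library of hippocampal cells from pooled mice that carry Aldh1l1-CreERT2, a tamoxifen-inducible recombinase active mainly in astrocytes, and a Cre-dependent tdTomato reporter. The hippocampus had been injected with a Cre-dependent AAV vector, named TIGRi-Hopx in the labels, that knocks down the homeodomain-only protein gene Hopx and carries EGFP. Cells were taken 3 weeks after tamoxifen and enriched by fluorescence sorting for the reporters. The series has 3 samples, each alone in its group. The anti-Flag and control IgG chromatin samples from primary astrocytes were not analysed here. The count matrix lists 6672 barcodes, against a stated aim of 6000 cells, and holds 41915122 UMIs. A barcode had a median of 5457 UMIs, with quartiles of 3421.5 and 8098, and a median of 2343 genes. After filtering and removal of 261 called doublets, 6224 cells with 39092951 UMIs remained. With 1 library, no difference has a replicate check and no p-value is given. Intervals are exact 95% Poisson or Clopper-Pearson limits, which cover counting error only, and cells are not replicates. For a share of 0, the limit given is instead the share that 3 cells would make, and it limits cells with a UMI, not cells that express the gene.

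The knockdown target Hopx (ENSMUSG00000059325) had 3504 UMIs in the cells analysed, or 89.6 (86.7 to 92.7) when scaled to 1000000 UMIs, written CPM below. At least 1 Hopx UMI was found in 1017 cells, 16.3% of all cells. There is no library without the vector, so the size of the knockdown cannot be measured from these counts.

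The design asks which astrocyte-like, progenitor-like and neuron-like states are present among the sorted cells. Immune and vascular cells made up most of the library, and astrocyte-like cells were a small part of it. Microglia-like cells were 2559 of the 6224 cells, or 41.1% (39.9 to 42.3). Endothelial-like cells followed with 1492 cells, or 24.0% (22.9 to 25.1). Ependymal-like cells, the ciliated lining of the ventricles, were 9.93% (9.20 to 10.7), and choroid plexus-like cells, which secrete cerebrospinal fluid, were 9.61% (8.89 to 10.4). Border macrophage-like cells were 6.88% (6.26 to 7.53). Astrocyte-like cells numbered 137, or 2.20% (1.85 to 2.60), and formed a single cluster. The neuron-like class held 20 cells, or 0.321% (0.196 to 0.496), and 0.548% with the stricter cell filter or 0.530% at a clustering resolution of 2.0. Oligodendrocyte-like cells were 102, B cell-like cells 85, T or NK cell-like cells 41 and mural-like cells 27. A further 117 cells in a pair of clusters stayed unnamed. The smaller of these clusters, 42 cells with a median of 975 UMIs, was led by genes that include Gfap, Fabp7 and Thrsp. No cluster met the naming rule for progenitor-like cells, a rule for whole clusters that sets no limit on single cells of that kind. The reporter sort sets these shares, so they do not describe the tissue.

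**Figure D1:**
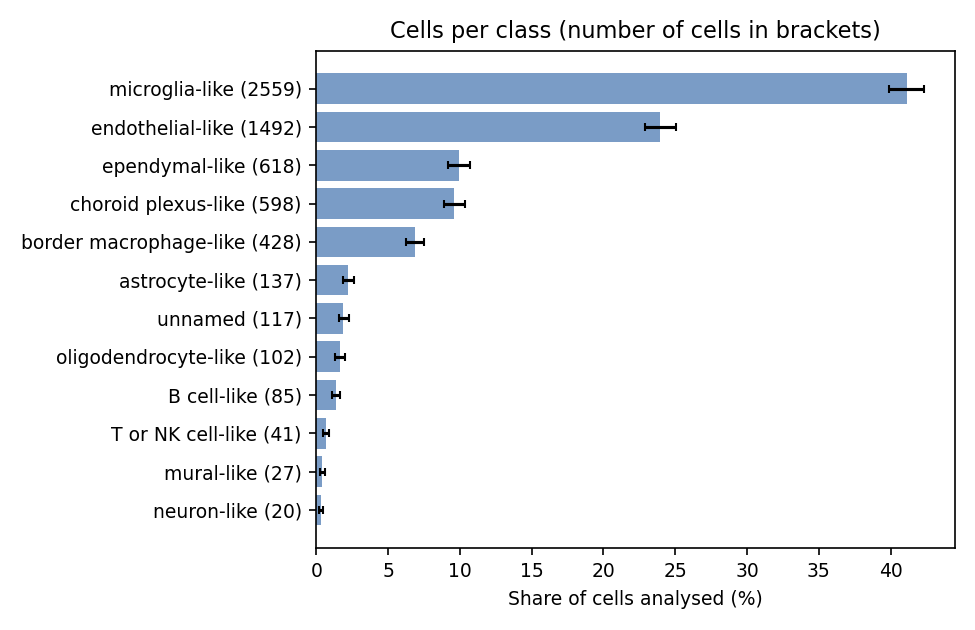
Share of the analysed cells in each named class, in percent, with exact 95% binomial intervals as bars. Microglia-like cells stand at 41.1%, astrocyte-like cells at 2.20% and neuron-like cells at 0.321%.

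Hopx RNA was compared between classes to show where the knockdown target is expressed. Astrocyte-like cells had the highest level of the named classes, 566 CPM (505 to 632). Choroid plexus-like cells had 334 CPM (320.3 to 348), oligodendrocyte-like cells 151 (124 to 181) and ependymal-like cells 142 (130.2 to 154). T or NK cell-like cells, in which Hopx is also known to be expressed, had 149 CPM (106 to 204). They also held RNA of other cell types, from which their Hopx was not separated. The choroid plexus gene Ttr was at 65.8 times the microglia-like level (62.8 to 68.9). The astrocyte genes Gfap and Slc1a2 were at 79.5 times (48.2 to 132) and 10.1 times (5.99 to 16.3). These genes were chosen after their values were seen. Microglia-like cells had 2.18 CPM (1.54 to 3.01), so the astrocyte-like level was 259 times higher (184 to 375). Neuron-like cells held 1 Hopx UMI, or 12.001 CPM (0.304 to 66.9), and their ratio to astrocyte-like cells was 0.0212 (0.000535 to 0.119). A Hopx UMI was found in 62.8% of astrocyte-like cells (54.1 to 70.9), at a median of 2968 UMIs, and in 1.29% of microglia-like cells (0.889 to 1.81), at a median of 6350. With each cell thinned to 2000 UMIs, the shares were 56% of 100 astrocyte-like cells and 0.290% of 2412 microglia-like cells. Choroid plexus-like cells had a Hopx UMI in 85.8% of cells before thinning, at a median of 10697 UMIs, and in 44.5% after it. Weighing cells equally lowered the astrocyte-like value from 566 to 465.9 CPM, with the choroid plexus-like value at 340.8 CPM under the same weighing.

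**Figure D2:**
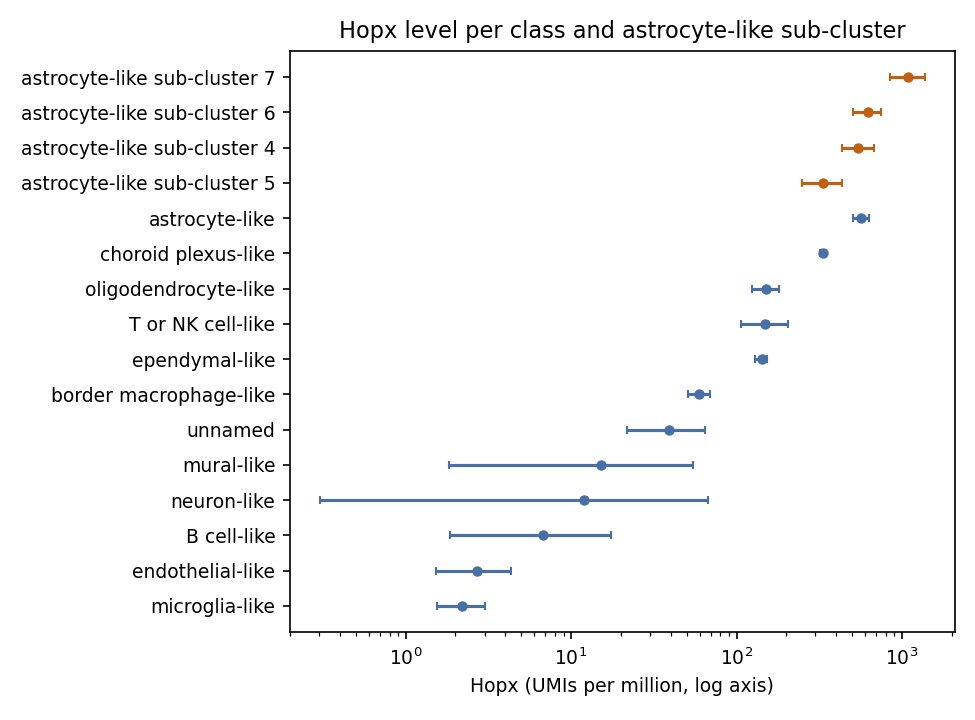
Hopx in CPM for each class and each astrocyte-like sub-cluster, on a log axis, with exact 95% Poisson intervals as bars. The astrocyte-like class stands at 566 CPM and the microglia-like class at 2.18, and the astrocyte-like sub-clusters run from 331 to 1082.

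Hopx was next compared within the astrocyte-like class, where transduced and untransduced astrocytes of the same mice are expected to sit side by side. One cluster held all astrocyte-like cells, so sub-clusters, added after the data were seen, are used and given by number and leading genes. The level differed between them. Sub-cluster 7, 18 cells led by Kcnip1, Ldb2 and Sgcz, had 1082 CPM (842 to 1369.6), 2.17 times the level of the other astrocyte-like cells (1.63 to 2.84). Myelin RNA was higher in it too, with Mobp at 4.31 times (1.78 to 9.85), and Aqp4, the astrocyte water channel, was at 0.428 times (0.301 to 0.594), both chosen after their values were seen. Sub-cluster 5, 37 cells led by the complement gene C3 and by Plac8 and S1pr3, had 331 CPM (249.6 to 431), 0.498 times the level of the rest (0.365 to 0.668). Of the 40 Plac8 UMIs in astrocyte-like cells, 29 lay in 2 cells of this sub-cluster, those with EGFP. Sub-cluster 4, 49 cells led by Fzd2, Pygm and Myorg, had 546 CPM (437 to 674), and sub-cluster 6, 33 cells led by Myoc and Cidea, had 619 (507 to 749). None of these differences can be tied to the vector, since EGFP UMIs were found in 2 of the 37 cells of sub-cluster 5 and in 0 of the other sub-clusters, which allows shares of cells with an EGFP UMI of up to 6.12%, 9.09% and 16.7% in sub-clusters 4, 6 and 7.

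Sub-cluster 5, with the lowest Hopx, had higher RNA of inflammatory and interferon-induced genes and lower RNA of cholesterol synthesis genes than the other astrocyte-like cells. Of the 22 measured interferon response genes, 21 were higher, in the sense that the interval of the ratio lay above 1, with a median log2 ratio of 3.72. Ifi44 had 40 UMIs against 0, a log2 ratio of at least 4.98 when 0 is set to 3 counts over the group, and Oasl2 was 26.8 times higher (13.6 to 60.3). Of 19 measured reactive astrocyte genes, 17 were higher, with a median of 2.58. Cxcl10 had 35 UMIs against 0, a log2 ratio of at least 4.79, and C3 had 35 against 1, a ratio of 82.7 (13.9 to 3360). The p53 and apoptosis list was higher in 9 of 13 genes, with a median of 1.49, and Phlda3, a p53 target, was 32.3 times higher (10.3 to 163). Immediate early and dissociation genes, which respond to cell handling, were higher in 9 of 18 and lower in 0, with a median of 1.24. Cholesterol synthesis genes were lower in 11 of 17, with a median of -1.40, among them Hmgcs1 at 0.138 times (0.0620 to 0.269). Hes5, a Notch target of neural progenitors and astrocytes, had 0 UMIs against 70. The medians with genes at 0 set to 3 counts were 3.75 for interferon response and 2.63 for reactive astrocyte genes. Sub-cluster 6 had higher S phase genes, 5 of 6 with a median of 1.97, higher nuclear genes of oxidative phosphorylation, 15 of 22 with a median of 0.67, and lower interferon genes, 15 of 22 with a median of -2.06 (-2.19 with genes at 0 set to 3 counts). Its leading genes also include the endothelial marker Flt1, and endothelial RNA was higher in it, with 18 Flt1 UMIs against 3, a ratio of 13.6 (3.96 to 71.9), and 12 Cldn5 UMIs against 1, a ratio of 27.1 (4.02 to 1161). Cldn5 was chosen after its values were seen, and the list differences were not separated from this RNA. Mki67, chosen after its values were seen, had 10 UMIs in sub-cluster 6, all in 1 cell.

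The design text names progenitor-like cells derived from astrocytes. With no cluster in that class, their gene lists could not be compared with those of astrocyte-like cells. Eomes, a factor of intermediate neuronal progenitors, was chosen after its values were seen. It had 14 UMIs in 5 cells of a sub-cluster led by Dcx, described below, and 0 in astrocyte-like cells.

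The neuron-like class was compared with the astrocyte-like class to show how far its cells differ from astrocytes. Its 20 cells, a cluster led by Reln, Kcnh7 and Cntnap2, held neuronal transcripts and very few astrocyte transcripts. Microglial RNA was present too, almost all of it in 1 cell: C1qa, a marker chosen after its values were seen, had 125 UMIs in 7 of the 20 cells, but 7 UMIs in 6 of the 19 cells of sub-cluster 2, which leaves that cell out. Of 24 astrocyte ion, water, transmitter and lipid handling genes, 22 were lower and 0 higher, with a median log2 ratio of -4.99 (-4.01 with genes at 0 set to 3 counts). Sparcl1 had 0 UMIs against 3621 and Clu 0 against 2943, log2 ratios of -7.49 and -7.19 at the 3-count bound, and the true ratios can be lower. Gfap, the astrocyte filament gene, had 0 UMIs against 725. Immature neuron cytoskeleton and adhesion genes were higher in 13 of 19 and lower in 2, with a median of 3.66 (2.01 with members held to at least 50 UMIs, 4.81 with cells weighed equally and 4.76 at a clustering resolution of 2.0). Gap43, a growth cone gene, had 56 UMIs against 1, a ratio of 375 (64.7 to 15084), and the RNA-binding gene Celf4 had 66 against 2, a ratio of 221 (58.8 to 1864). Of the markers used for naming, Dcx, Neurod1, Prox1 and Rbfox3 had 0 UMIs in the neuron-like class and Sox11 had 1. Syt1 had 116 UMIs there, Stmn2 40 and Tubb3 17. These markers were chosen after their values were seen. Synaptic vesicle and postsynaptic density genes were higher in 12 of 18 and lower in 1, with a median of 1.76 (1.72 at the bound, 0.72 with members held to at least 50 UMIs and 2.68 at resolution 2.0). Slc17a6, a vesicular glutamate transporter, had 27 UMIs against 0, a log2 ratio of at least 5.91, and Syn1 had 11 against 0. Voltage-gated channel genes were higher in 5 of 10 and lower in 2, with a median of 2.42 (2.38 at the bound), and Scn3a had 14 UMIs against 0.

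Neurogenic transcription factors went both ways in the neuron-like class. Of 11 measured, 6 were higher and 5 lower, with a median of 2.29 (2.27 at the bound). Nhlh2 had 44 UMIs against 0 and Myt1l 38 against 0, log2 ratios of at least 6.62 and 6.41, and Tbr1, a cortical glutamatergic factor, had 10 against 0. Sox5, on the same list, had 0 UMIs against 205. With members held to at least 50 UMIs, the median was -4.80 over 4 genes, and that of the voltage-gated channels was -1.88 over 3. That limit counts UMIs of both groups together, so it drops Nhlh2, Myt1l and Tbr1 and keeps Sox5. The astrocyte-like group holds more cells and UMIs, so the limit favours genes high in it. Gliogenic transcription factors were lower in 10 of 14 and higher in 3, with a median of -1.61 (-1.71 at the bound), and Rorb had 0 UMIs against 498 and Sox6 0 against 317. Quiescent neural stem cell genes were lower in 7 of 10, with a median of -3.25 (-0.76 at the bound). Reactive astrocyte genes were lower in 10 of 20 and higher in 3, with a median of -2.68 (-0.58 at the bound). Without the cell with microglial RNA, 9 were lower and 0 higher, with a median of -2.49 (-0.52 at the bound). Cholesterol synthesis genes were lower in 9 of 17, with a median of -1.45 (-1.43), and fatty acid oxidation genes in 7 of 16, with a median of -1.59 (-1.33). Immediate early and dissociation genes were higher in 14 of 20 and lower in 1, with a median of 1.73, and in 11 of 19 without that cell, with a median of 1.76. The unfolded protein and integrated stress response list was higher in 7 of 13 and lower in 1, with a median of 1.16. Interferon response genes were lower in 7 of 22, with a median of -0.65 (-0.66). Nuclear genes of oxidative phosphorylation were higher in 8 of 22 and lower in 1. Their median of 0.56 exceeded 59.4% of the random lists of like expression. Glycolysis genes were higher in 5 of 19 and lower in 4, with a median of 0.01 (-0.02 in ratios without the 0.5 UMI added). The Notch pathway was lower in 4 of 11 and higher in 1, with a median of -1.78 (-0.92 at the bound). The BMP, TGF-beta and Id genes were lower in 6 of 16 and higher in 1, with a median of -0.86 (-0.53), and the Wnt pathway in 2 of 14 and higher in 1, with a median of -1.15 (-0.33). The p53 and apoptosis list was higher in 3 of 14, with a median of 0.37 that exceeded 76.0% of the random lists, S phase genes in 0 of 6, with a median of 0.94, and 2 measured G2 and M phase genes went opposite ways. Under the rule for named genes, 70 list genes were higher and 79 lower.

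**Figure D3:**
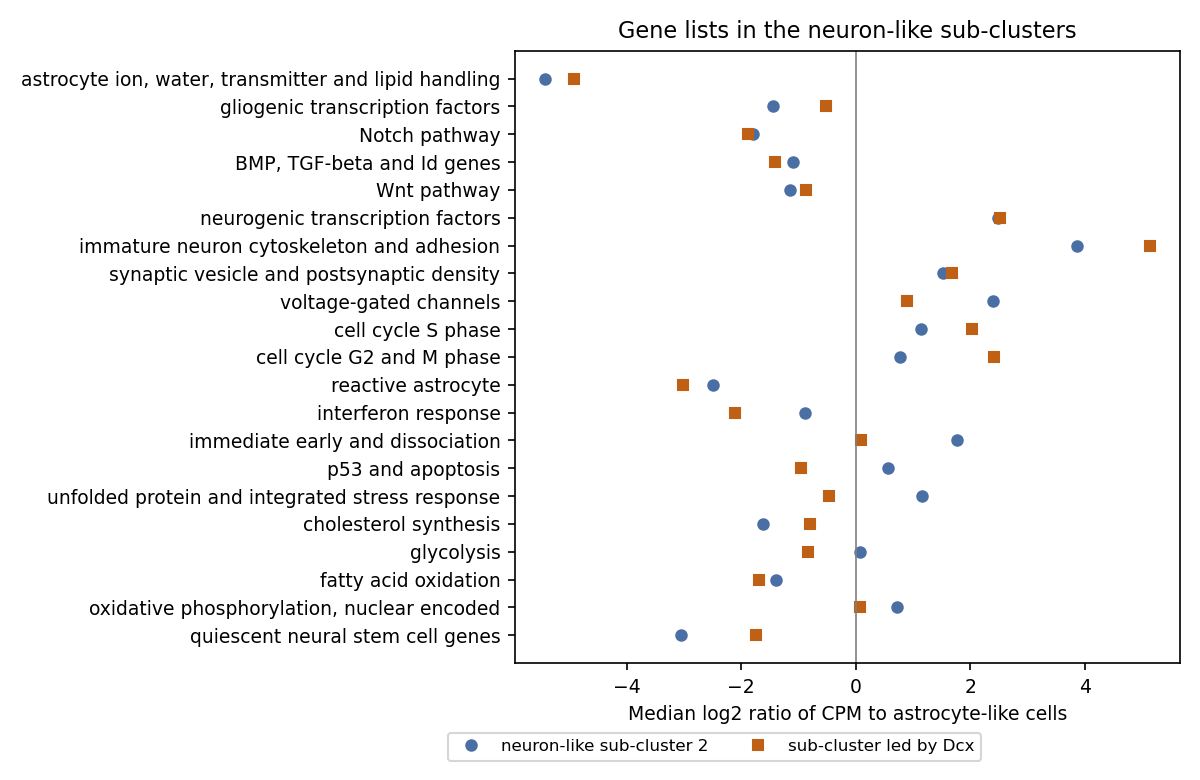
Median log2 ratio of CPM to astrocyte-like cells for each gene list, for neuron-like sub-cluster 2, 19 cells led by Trp73 and Lhx1, and for the sub-cluster led by Dcx. The astrocyte handling list stands at -5.42 and -4.92 (-3.90 and -4.72 with genes at 0 set to 3 counts) and the immature neuron list at 3.86 and 5.13.

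A sub-cluster of 13 cells within the oligodendrocyte-like cluster was also neuron-like by its markers. It was led by Dcx, Sox11, Rbfox3, Tac2 and Neurod1, with 47 Dcx UMIs in 12 of its 13 cells against 2 Dcx UMIs in 2559 microglia-like cells and 0 in astrocyte-like cells. Immature neuron cytoskeleton and adhesion genes were higher than in astrocyte-like cells in 21 of 22, with a median log2 ratio of 5.13. Igfbpl1, a gene of newborn neurons, had 161 UMIs against 3, a ratio of 392 (132 to 1919), and Cd24a had 19 against 1, a ratio of 139 (22.0 to 5762). Neurogenic transcription factors were higher in 7 of 10 and lower in 2, with a median of 2.53 (2.51 at the 3-count bound). Myt1l had 62 UMIs against 0, a log2 ratio of at least 7.24, and Neurod2 had 9 against 0. S phase genes were higher in 7 of 9, with a median of 2.03. Astrocyte handling genes were lower in 23 of 24, with a median of -4.92 (-4.72). Apoe was at 0.00778 times the astrocyte-like level (0.00445 to 0.0126), and Id3 had 0 UMIs against 363. Slc1a2, the astrocyte glutamate transporter, was chosen after its values were seen. It had 42 UMIs in 10 of the 13 cells, or 549 CPM (396 to 742), against 10152 in astrocyte-like cells and 7.56 in microglia-like cells. Hopx had 1 UMI, 13.1 CPM (0.331 to 72.8), a ratio of 0.0231 to astrocyte-like cells (0.000583 to 0.130). The sub-cluster was found after the data were seen, and at a clustering resolution of 2.0 its cells joined the neuron-like class, which then held 0.530% of cells.

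The reporters were examined to separate transduced from untransduced cells, since EGFP is carried by the vector and tdTomato marks recombination. Few cells held an RNA of either one. EGFP UMIs were found in 67 cells, or 1.08% (0.835 to 1.37), with 91 UMIs, and tdTomato UMIs in 224 cells, or 3.60% (3.15 to 4.09), with 351 UMIs. Only 6 cells held both. Ependymal-like cells held 70.1% of the EGFP-positive cells. An EGFP UMI was found in 47 of 618 ependymal-like cells, or 7.61% (5.64 to 9.99), at a median of 5809.5 UMIs, against 1 of 2559 microglia-like cells, or 0.0391% (0.000989 to 0.218), at a median of 6350. After thinning to 2000 UMIs these shares were 2.26% and 0%. EGFP UMIs were found in 2 of 137 astrocyte-like cells, or 1.46% (0.177 to 5.17), in 5 of 102 oligodendrocyte-like cells, or 4.90% (1.61 to 11.1), and in 2 of 20 neuron-like cells, or 10% (1.23 to 31.7). The thinned shares were 1%, 2.13% and 5.88%. For tdTomato, astrocyte-like cells had the highest level, 71.6 CPM (51.2 to 97.54), with a UMI in 27 of 137 cells, or 19.7% (13.4 to 27.4). Choroid plexus-like cells had 25.2 CPM (21.5 to 29.3) and a UMI in 13.2% of cells (10.6 to 16.2). Ependymal-like cells had 13.7 CPM and 5.83% of cells. Microglia-like cells had 1.36 CPM (0.861 to 2.04) and 0.821% of cells (0.509 to 1.25). After thinning, the tdTomato shares were 11% in astrocyte-like, 6.14% in choroid plexus-like, 2.44% in ependymal-like and 0.290% in microglia-like cells. Of the tdTomato-positive cells, 35.3% were choroid plexus-like, 16.1% ependymal-like, 16.1% endothelial-like and 12.1% astrocyte-like. B cell-like cells had a tdTomato UMI in 7 of 85 cells, or 8.24% (3.38 to 16.2), and in 1.27% after thinning. No neuron-like cell held a tdTomato UMI, and 0 of 20 cells allows a share with a UMI of up to 15%. In the sub-cluster led by Dcx, 2 of 13 cells held tdTomato, or 15.4% (1.92 to 45.4), and 1 of 12 did after thinning, while 0 of 13 held EGFP, which allows a share with a UMI of up to 23.1%.

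**Figure D4:**
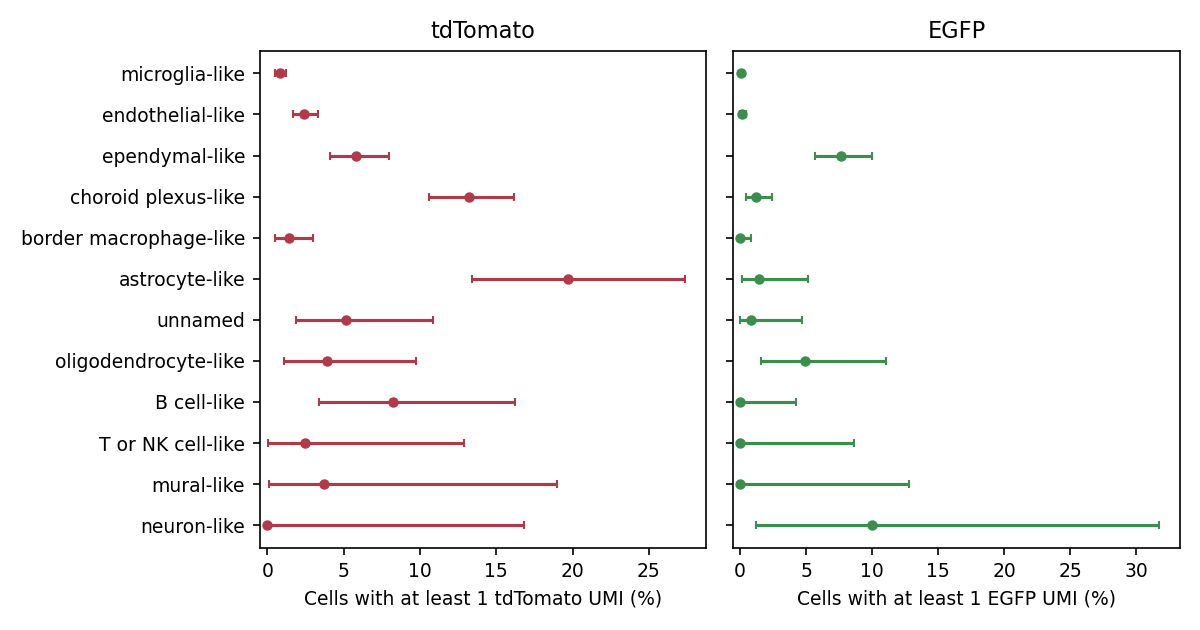
Percent of cells with at least 1 EGFP UMI and with at least 1 tdTomato UMI in each class, with exact 95% binomial intervals as bars. EGFP is highest among the large classes in ependymal-like cells, 7.61%, and tdTomato in astrocyte-like cells, 19.7%.

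The planned comparison of astrocyte-like cells with and without EGFP rested on 2 cells against 135. Hopx was 440.0 CPM in the first and 571 in the second, a ratio of 0.770 (0.366 to 1.44). After thinning, 1 of 2 EGFP-positive cells and 55 of 98 EGFP-negative cells held a Hopx UMI, or 50% (1.26 to 98.7) and 56.1% (45.7 to 66.1). A difference in Hopx was not detectable at this depth. Both EGFP-positive cells lay in sub-cluster 5, so the interferon response genes, higher in 10 of 22 with a median log2 ratio of 1.88 (1.97 at the 3-count bound), cannot be separated from that sub-cluster. By tdTomato, the 27 positive astrocyte-like cells had 623 CPM of Hopx and the 110 negative cells 544, a ratio of 1.15 (0.893 to 1.46), at median depths of 5816 and 2727.5 UMIs. The BMP target Id3 was 2.96 times higher in the positive cells (2.39 to 3.66). Nuclear genes of oxidative phosphorylation were higher in 8 of 22, with a median of 0.49, and the neuronal cytoskeleton gene Stmn1 was at 0.212 times the level of negative cells (0.0828 to 0.457). The myelin genes Mbp and Mobp, chosen after their values were seen, were lower as well, with 1 UMI against 62, a ratio of 0.0411 (0.00102 to 0.238), and 1 against 27, a ratio of 0.0944 (0.00230 to 0.573). Further RNA lay wholly or almost wholly in the negative cells, with 0 against 21 UMIs of the endothelial gene Flt1, 0 against 13 of Slco1a4, 1 against 12 of Cldn5, and 0 against 10 each of the cell cycle genes Mki67 and Top2a. Interferon response genes were lower in 3 of 22, with a median of -0.46 (-0.49 with genes at 0 set to 3 counts). RNA of other cell types in the negative cells was not separated from the differences in Stmn1 and in oxidative phosphorylation genes. Sub-cluster 6 held 20 of the 40 tdTomato UMIs of astrocyte-like cells, and sub-clusters 4, 5 and 7 held 11, 9 and 0. Sub-cluster 6 by itself had 8 of 16 BMP, TGF-beta and Id genes and 15 of 22 oxidative phosphorylation genes higher, and 15 of 22 interferon genes lower. The differences by tdTomato in Id3 and in these lists were not separated from sub-cluster 6.

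The vector was most often seen in ependymal-like cluster 3, so EGFP-positive and EGFP-negative cells were compared there. This comparison was added after the reporter counts were seen. The 44 positive cells had less Hopx RNA and more RNA of stress response and p53 target genes than the 414 negative cells. Hopx was 45.5 CPM (25.5 to 75.05) against 121 (107 to 135), a ratio of 0.377 (0.208 to 0.632). Among 3461 genes of similar UMI totals in the cluster, 15 had a ratio as low, or 0.433%. A Hopx UMI was found in 22.7% of positive cells, at a median of 6401.5 UMIs, and in 37.0% of negative cells, at a median of 5283. After thinning the shares were 9.30% (2.59 to 22.1) and 14.4% (11.01 to 18.4), and the ratio was 0.651 (0.205 to 1.60), which includes 1. Microglia-like cells, the background, had a Hopx UMI in 1.29% of cells before thinning and 0.290% after it.

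The unfolded protein and integrated stress response list was higher in 10 of 16 genes in these EGFP-positive cells, with a median log2 ratio of 0.82, above all 10000 random lists. Chac1, Trib3 and Ddit3, targets of the stress factor Atf4, were 10.5 (5.03 to 22.4), 9.002 (4.94 to 16.6) and 3.46 (2.41 to 4.90) times higher. The p53 and apoptosis list was higher in 10 of 16, with a median of 0.88, and the cell cycle inhibitor gene Cdkn1a was 4.31 times higher (3.33 to 5.54) and Gdf15 6.31 times (3.95 to 10.0). The split by tdTomato in the same cluster gave higher values of some of these genes too, with Gdf15 at 4.63 times (2.61 to 7.86), Ddit3 at 2.498 times (1.51 to 3.94) and Cdkn1a at 2.33 times (1.60 to 3.31). The splits can share cells, since 5 ependymal-like cells held both reporters, and tdTomato-positive cells without EGFP were not compared alone. Immediate early and dissociation genes were higher in 17 of 20, with a median of 0.73, against 12 of 20 and a median of 0.66 in the split by tdTomato, and interferon response genes in 20 of 22, with a median of 0.73. The interferon median was -0.00630 at a clustering resolution of 2.0 and -0.00519 with at least 2 EGFP UMIs per positive cell. Reactive astrocyte genes were higher in 8 of 22 and lower in 4, with a median of 0.46 (0.35 in ratios without the 0.5 UMI added), and the heat shock gene Hspb1 was 4.04 times higher (3.38 to 4.82). Astrocyte handling genes were lower in 8 of 21, with a median of -0.53, and the lipid carriers Apoe and Clu were at 0.431 (0.406 to 0.458) and 0.478 times (0.428 to 0.533). The axonal membrane gene Basp1 was at 0.255 times (0.115 to 0.491). By tdTomato, 24 positive cells of the same cluster had a Hopx ratio of 1.20 (0.751 to 1.84) to 434 negative cells. EGFP-positive cells of other classes were few. Hopx was 1.49 times higher (1.04 to 2.07) in 7 EGFP-positive choroid plexus-like cells. Markers of other cell types, chosen after their values were seen, were higher in the same cells, with the myelin genes Mbp at 3.75 times (1.97 to 6.504) and Mobp at 8.90 times (2.77 to 22.2) and the ciliary gene Dynlrb2 at 2.24 times (1.32 to 3.57), while Ttr was at 0.713 times (0.6998 to 0.727). In this class the Hopx ratio was not separated from RNA of other cell types. The Hopx ratio was 1.02 (0.366 to 2.29) in 5 oligodendrocyte-like cells. The 97 EGFP-negative cells of the latter class include the 13 cells led by Dcx, so that comparison is not within 1 cell type.

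**Figure D5:**
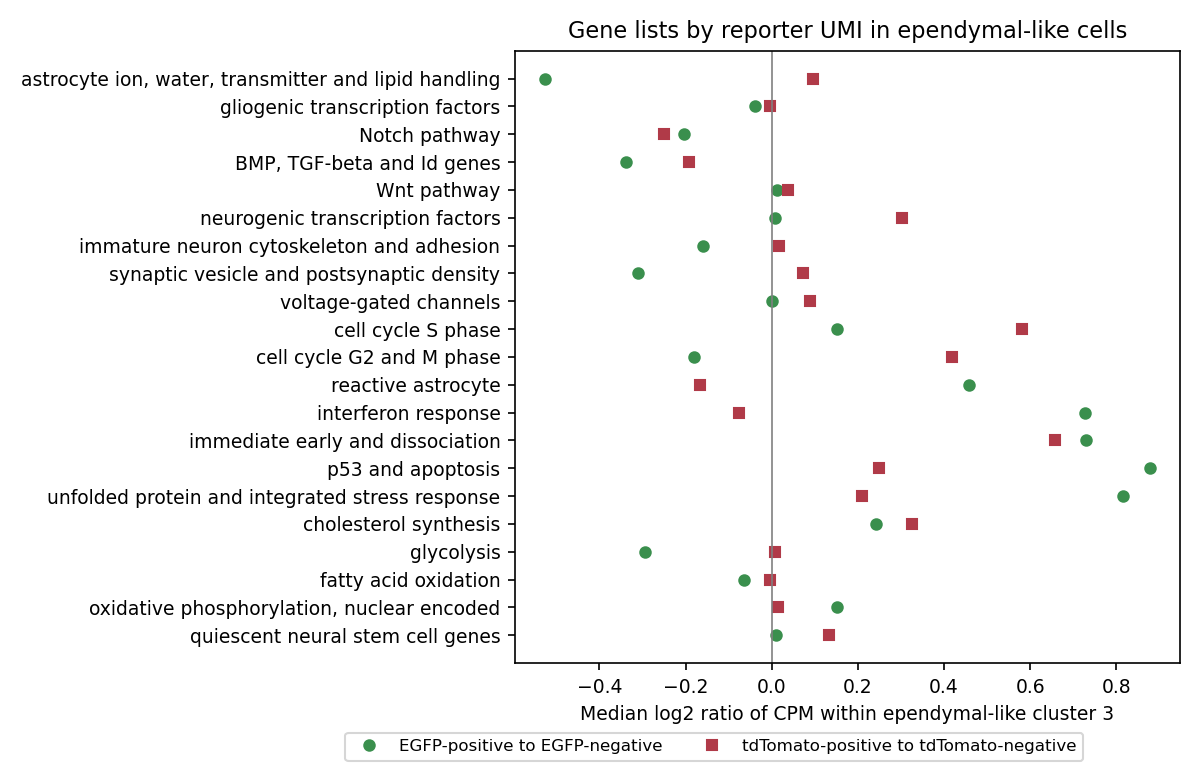
Median log2 ratio of each gene list in ependymal-like cluster 3, for cells with against without an EGFP UMI and for cells with against without a tdTomato UMI. For EGFP the p53 list stands at 0.88 and the stress response list at 0.82, and for tdTomato at 0.25 and 0.21, while the immediate early list stands at 0.73 for EGFP and 0.66 for tdTomato.

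Cells with RNA of cell cycle genes were counted in each class, since the design text names a progenitor-like state. The count rests on UMIs of the cycle lists alone and does not measure division. Cells with at least 3 UMIs summed over the S phase and the G2 and M phase lists, after thinning to 2000 UMIs, were 3 of 100 astrocyte-like cells, or 3% (0.623 to 8.52), and 213 of 2412 microglia-like cells, or 8.83% (7.73 to 10.0). Border macrophage-like cells had 57 of 411, or 13.9% (10.7 to 17.6), ependymal-like cells 38 of 574, or 6.62% (4.73 to 8.97), and choroid plexus-like cells 3 of 586, or 0.512% (0.106 to 1.49). Without thinning, the rule took 20 of 137 astrocyte-like cells and 1323 of 2559 microglia-like cells. In the neuron-like class 2 of 17 cells passed after thinning, although Mki67, Top2a and Cdk1 had 0 UMIs there. The sub-cluster led by Dcx had 1 of 12 cells that passed after thinning, or 8.33% (0.211 to 38.5), and 5 of 13 without thinning. It held 11 Top2a, 5 Mki67 and 3 Cdk1 UMIs at full depth. With at least 2 UMIs the shares were 9% in astrocyte-like and 25.2% in microglia-like cells.

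Joint detection of astrocyte and neuron markers was counted to look for cells between both states. Cells with at least 2 markers of each kind, after thinning, were 2 of 100 astrocyte-like cells, or 2% (0.243 to 7.04), both in sub-cluster 7. Ependymal-like cells gave a like share, 14 of 574 or 2.44% (1.34 to 4.06), and microglia-like cells gave 0 of 2412. The neuron-like class gave 0 of 17, and the sub-cluster led by Dcx 2 of 12. All 5699 cells deep enough for the count gave 20, or 0.351% (0.214 to 0.541). In sub-cluster 7 the only neuron markers with UMIs were Map2, with 33, and Prox1, with 7. Its 2 cells with both marker kinds thus rest on these genes. Map2 was at 365 CPM over all astrocyte-like cells, against 720 in neuron-like cells. The count therefore does not show astrocyte-like cells between both states.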

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

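The tests of reporter RNA in this part were chosen after the reporter counts were seen. Barcodes left out of the report's comparisons hold signal too, and enter only the alternatives with doublets kept or with a looser filter. The 261 called doublets hold 19 tdTomato UMIs (7.12 CPM), in 13 barcodes or 4.98% (2.68 to 8.37), and 281 Hopx UMIs (105 CPM). The 187 barcodes removed by the filter hold 9 Hopx UMIs (58.3 CPM). These values stand out only because they lie in data set aside before the comparisons, and their difference from the cells analysed was not tested.

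Reporter RNA was unequal between classes of a library sorted for reporter protein, and 285 cells, or 4.58% (4.07 to 5.13), held a UMI of either reporter. Free tdTomato RNA as the source of the UMIs in astrocyte-like cells is argued against, since their tdTomato level was 52.8 times that of microglia-like cells (30.8 to 92.3), against 1.23 times (1.03 to 1.45) for Ttr, a choroid plexus transcript found in all classes. An equal number of tdTomato molecules in every sorted cell is argued against too, since astrocyte-like cells held 32.5 times as many tdTomato UMIs per cell (19.0 to 56.8). The passage of cells without reporter RNA through the sort, for example by autofluorescence of microglia, may explain the 41.1% microglia-like cells, but no value per cell from the sort is at hand and this was not tested. Recombination outside astrocytes, in choroid plexus and ependymal cells, could explain their tdTomato and stays open as well.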

How the results depend on the processing

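The alternatives for the comparison of ependymal-like cells by EGFP and for the sub-cluster led by Dcx were added after the data were seen, and the others were chosen before the data were examined. No paired analysis was possible because the library is alone in its group and no test across samples exists. Alternatives for progenitor-like against astrocyte-like lists gave no value, since no cluster took that name under the 7 clustering alternatives. Depth limits the detection of rare RNA: at 2000 UMIs per cell, EGFP was left in 2.26% of ependymal-like cells and tdTomato in 11% of astrocyte-like cells.

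The astrocyte handling list stayed lower in neuron-like cells under every alternative run, from -5.49 to -4.89. At full depth, under the strict filter and with doublets kept, astrocyte-like cells with tdTomato were 19.6% to 24.3% and ependymal-like cells with EGFP 7.29% to 7.82%. The Hopx ratio by EGFP stayed below 1, from 0.267 with cells weighed equally to 0.651 after thinning, where its interval (0.205 to 1.60) includes 1. The stress response list stayed higher (0.45 to 0.85), as did the p53 list (0.69 to 1.18).

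Other values moved or reversed, and beyond what the 50-UMI limit itself implies the cause was not tested. With list members held to 50 UMIs, neurogenic transcription factors reversed to -4.80 and voltage-gated channels to -1.88, immature neuron genes were at 2.01 and synaptic genes at 0.72. This limit counts UMIs of both groups together, and the astrocyte-like group is the larger. It drops genes such as Nhlh2 and Myt1l, which had no UMI in astrocyte-like cells, and keeps Sox5, which had none in neuron-like cells. With cells weighed equally, Hopx was 465.9 CPM in astrocyte-like and 120.9 in ependymal-like cells, and immature neuron genes were at 4.81. With 2 UMIs as threshold for cell cycle genes, astrocyte-like cells were at 9% and microglia-like cells at 25.2%. Microglia-like cells were 39.2% with the loose filter, 42.4% with the strict filter, 39.5% with doublets kept and 43.0% at resolution 0.5. The strict filter gave 1.83% astrocyte-like and 0.548% neuron-like cells. Resolution 2.0 gave 0.530% neuron-like cells, with immature neuron genes at 4.76 and synaptic genes at 2.68. In the EGFP comparison, interferon and immediate early genes were at 1.00 and 0.49 over all ependymal-like clusters, 0.34 and 0.52 against the nearest EGFP-negative cells, and 0.47 and 0.82 after thinning. With at least 2 EGFP UMIs interferon reversed to -0.00519, with immediate early genes at 1.14 and stress response genes at 0.45. At resolution 2.0 interferon reversed to -0.00630, with immediate early genes at 0.95, and with doublets kept immediate early genes were at 0.45.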

Other observations

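In this part the tests on neuron-like cells, and the comparisons of microglia-like and border macrophage-like clusters, were chosen after the results were seen. Microglia-like cells formed clusters with distinct programs, each compared here with the other microglia-like cells. Cluster 11, 143 cells led by Cxcl11, Cxcl9 and Ccl5, had higher RNA of 20 of 22 interferon response genes, with a median log2 ratio of 1.21, and Rsad2, an antiviral gene, was 7.79 times higher (7.21 to 8.42). Cluster 12, 481 cells that express the homeostatic gene P2ry12 among their leading genes, had lower RNA of 20 of the 22, with a median of -2.02, and Apoe was at 0.101 times (0.0980 to 0.104). Its immediate early and dissociation genes were higher in 19 of 20, with a median of 0.90, and Jun was 5.27 times higher (5.15 to 5.40). Cluster 2, 249 cells led by Spp1, Lpl and Gpnmb, had higher RNA of 8 of 17 cholesterol synthesis genes, with a median of 0.52, and Apoe was 2.92 times higher (2.90 to 2.94).

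Hopx was also present in immune cells outside microglia. Border macrophage-like cluster 13, 195 cells led by Saa3, Chil3 and Clec4e, had 93.5 CPM (79.6 to 109). Cluster 14, 233 cells led by genes that include Cd163 and Lyve1, had 2.91 CPM (0.600 to 8.51).

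Neuron-like cells in a library sorted for an astrocyte lineage may be neurons taken along by the sort, droplets with 2 cells, or astrocyte-derived cells. Droplets of an astrocyte and a neuron are argued against, since the summed astrocyte marker level was 0.00834 times that of astrocyte-like cells (0.00476 to 0.0135) in the neuron-like cluster and 0.0409 times (0.0320 to 0.0515) in the sub-cluster led by Dcx. This does not cover droplets with other cells, and 1 neuron-like cell carried microglial RNA. Origin of the Dcx-led cells from recombined astrocytes cannot be told apart from other sources, since 15.4% of 13 cells held tdTomato (1.92 to 45.4), an interval that spans the 13.2% (10.6 to 16.2) of choroid plexus-like cells. With 13 cells this share is too loosely bounded to decide. Their 3 tdTomato UMIs put the level at 28.9 times that of microglia-like cells (5.55 to 95.6). The ratio to astrocyte-like cells was 0.547 (0.108 to 1.72). Neurons already present, such as newborn granule cells of the adult dentate gyrus and Cajal-Retzius cells, which express Reln and Trp73, stay open and untested, as no library without the vector is part of the series. No cell of the neuron-like class held a tdTomato UMI, but 2 cells held EGFP, with 2 UMIs, both in sub-cluster 2. Reln led the neuron-like cluster and Trp73 its sub-cluster 2. The leading genes of that class thus include those of Cajal-Retzius cells, while the origin of its cells was not tested.

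Lower Hopx in EGFP-positive ependymal-like cells is what knockdown by the vector predicts, with a ratio of 0.377 (0.208 to 0.632). The test was written before that ratio was seen. Genes not targeted were lower in the same cells too, with Basp1 at 0.255 times (0.115 to 0.491) and Apoe at 0.431 times (0.406 to 0.458). Under the rule for named genes, Hopx was among 5 lower list genes, with 21 higher. A loss of RNA not specific to Hopx was not tested. A general effect of depth in cells with a reporter UMI is argued against by the tdTomato ratio of 1.20 (0.751 to 1.84), whose interval excludes 0.377. A stressed state with low Hopx among cells without an EGFP UMI is argued against too. The EGFP-negative cells with the most stress and p53 list UMIs, 82 against 293 cells, had a ratio of 1.13 (0.845 to 1.499). Cluster 3 held 61 EGFP UMIs in its 44 positive cells, so cells without an EGFP UMI can still carry the vector. Stress caused by the vector itself is not covered by this split. Chance variation between cells and mice stays open, because the intervals cover counting error only and the ratio after thinning was 0.651 (0.205 to 1.60). Choroid plexus-like cells went the other way, with a ratio of 1.49 (1.04 to 2.07) from 7 EGFP-positive cells that also held more myelin and ciliary RNA. In those 7 cells the stress response list was higher in 0 of 14 genes and lower in 2, and the p53 list was higher in 0 of 14. The source of the stress response in EGFP-positive ependymal-like cells was not tested.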
